A study of Rattus norvegicus with 32 samples.

How the data were processed

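The series held liver RNA sequencing of 32 rats, 4 in each of 8 groups by sex, genotype (CBG knockout, made by genome editing, or WT) and age (30 or 60 days), under basal conditions. Per the labels, RNA was extracted with Trizol and libraries were made with a stranded messenger RNA kit. Per the submitters' processing notes STAR, Cufflinks, limma and the rat assembly Rnor_5.0 were used; their roles, versions and the gene annotation are not given in the sources used here. The authors deposited a table of raw counts, whose unit is counts of reads per gene, with 17327 genes and 2 further lines for reads on no feature and ambiguous reads. They also deposited a table of log2 values, log2 CPM of 11344 genes, which equalled values recomputed from the counts (0.5 added to each count and 1 to the total) to 5.0e-09 and carried no scaling between libraries. The filter that left 11344 genes is not given in the sources used here. Reads on no feature came to 18.05% to 21.18% and ambiguous reads to 0.262% to 0.648%. Reads themselves were not analysed here, and no genome of that assembly was at hand, so alignment, strand of counting and coordinates in that assembly were not examined. The order of genes along chromosomes, used only for the neighbours of Serpina6, came from a RefSeq gene table. Reads shared within gene families (Cyp2c, Cyp3a, Cyp4a, Sult2a, Ugt2b, Mup) could not be parted from the counts, so the values of single members depend on the authors' counting.

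Of the 17327 gene names 14815 were found as a symbol and 2100 as a synonym in a RefSeq gene table, and 26 had been turned into dates by a spreadsheet and were kept as they stood. In all 2985 genes had no read in any library. The 10 most abundant genes took 26.86% to 33.64% of gene reads, albumin 12.6% to 20.12%. Groups followed the labels. Replicate numbers in the text follow the order of the samples in the series and do not link animals across groups, so no paired analysis was possible because the labels pair no animals. Sample titles had another form at each age, and no batch was labelled.

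Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (minimum count 10, smallest group 4), trimmed mean of M-values (TMM) scaling, and a robust quasi-likelihood fit of 8 group means to all 32 libraries with 24 residual degrees of freedom. The biological coefficient of variation was 0.148. Contrasts were KO against WT in each sex and age, males against females in each genotype and age, 60 against 30 days in each sex and genotype, the sex-by-genotype interaction at each age and the age-by-genotype interaction in each sex. Genes at a Benjamini-Hochberg adjusted p below 0.05 within a contrast were called, and a stricter count asked for a log2 fold change of at least 1 in size. CPM levels are TMM-scaled. Gene lists were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01 and with an estimated one, and with fry, adjusted over 29 lists. The lists covered male-biased and female-biased liver genes, glucocorticoid receptor targets, steroid metabolism, growth hormone signalling, gluconeogenesis, fatty acid synthesis, cholesterol synthesis and bile acids. Others covered PPAR-alpha targets, xenobiotic metabolism, the clock, acute phase, interferon, cell cycle, fetal liver, the urea cycle, pericentral and periportal hepatocytes, Kupffer cells, lymphocytes, neutrophils, stellate cells, endothelial cells, cholangiocytes, erythroid cells, tissue markers (pancreas, adipose, muscle), handling and endoplasmic reticulum stress. Of 13 mitochondrially encoded genes 0 were in the table, so that list could not be tested, and of 11 sex chromosome genes 1 was. Lists, contrasts, tests and the rule for named genes were fixed before the data were examined.

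Named genes were Serpina6 and the following. In each contrast they were the 8 called genes with the largest positive and the 8 with the largest negative fold change (4 and 4 for age, for the sex contrasts of KO and for age by genotype) with a symbol, a mean of at least 1 CPM in the higher group and, for contrasts of 2 groups, no overlap between the groups. To these came up to 4 called members of each list with the smallest adjusted p, and Cyp2c11, Cyp2c12, Nr3c1, Hsd11b1, Ghr and Igf1 whatever their value. A gene named in one contrast could be given in others. The sex score was the mean log2 CPM (prior count 2) of the male-biased list minus that of the female-biased list, compared by exact permutation of the 8 libraries.

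The design was tested on simulated data with the dispersions of these libraries, in which 67, 67 and 66 of 11002 genes were changed 1.5-, 2- and 4-fold. For KO against WT in 60-day females edgeR recovered 53.7% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 93.9% of those changed 4-fold, with 6 false calls among 10802 unchanged genes. The sex-by-genotype test at 60 days recovered 22.4%, 61.2% and 86.4% with 5 false calls. The simulation gave each gene 1 spread for all groups, as the fit does. It therefore does not measure false calls where the groups differ in spread. For 60-day females a fit to the 8 libraries compared recovered 41.8%, 82.1% and 92.4% of the simulated changes, with 7 false calls. On the real counts that fit called 56 genes against 745. The depth was 12951969 to 21954929 reads on genes per library.

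Alternatives were DESeq2's size factors and upper-quartile scaling within edgeR, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, and limma-voom. Others were limma on the authors' log2 table, fits to the 16 libraries of an age or the 8 compared, and leaving out each library in turn. The number after the hyphen in the 30-day titles was a covariate in the fit to the 16 libraries of that age. Chosen after the data were seen were the mean of the 4 KO contrasts, leaving out 2 libraries together, the list tests with libraries left out, the female version of the divided WT libraries, the counts and score of both versions without Serpina6, and lists of retina, brain myelin, pineal gland and clock phases. Other splits of the libraries were counted for each contrast. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 drew the figures. No library was left out of the tests reported first.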

Results

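Liver messenger RNA was sequenced from 32 Sprague Dawley rats, in 8 groups of 4 that combined sex, genotype and age. The knockout (KO) rats carried a disruption, made by genome editing, of Serpina6, the gene for corticosteroid-binding globulin (CBG), a protein that the liver secretes and that carries corticosterone in blood. Wild-type (WT) and KO livers were collected at 30 and at 60 days of age, and the title of the series names the sex difference of the adult liver as its subject. Between 12951969 and 21954929 reads per library were counted on genes, at least 16806943 at 30 days and at most 17133332 at 60 days. Within groups, log2 expression of replicate libraries correlated across genes with r between 0.966 and 0.991. The counts of every replicate pair differed by more than sampling noise (chi-square per degree of freedom 11.1 to 58.6), and each library was kept as 1 replicate. The first principal component, with 36.5% of the variance, ordered the libraries by age, and the second, with 26.9%, by sex. Fold changes below are log2 values ± SE from edgeR's quasi-likelihood test with 4 libraries per group. Levels are mean CPM (counts scaled to the size of the library) ± SD (n = 4), and adjusted p-values follow Benjamini and Hochberg over the 11002 genes tested.

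Serpina6 transcripts were 7.75 to 16 times lower in KO than in WT liver in every combination of sex and age. In females the level was 58.7 ± 16.1 CPM in KO against 706 ± 174 CPM in WT at 30 days, and 106 ± 19.6 against 1148 ± 249 CPM at 60 days. In males it was 31.8 ± 6.63 against 510 ± 41.4 CPM at 30 days, and 62.8 ± 24.5 against 487 ± 63.4 CPM at 60 days. The residual transcript thus stood at 8.32%, 9.24%, 6.24% and 12.9% of WT in the same order. The highest KO library lay below the lowest WT library in all 4 comparisons, so the genotype labels of all 32 libraries matched the level of the target. The fold changes were -3.59 ± 0.26 in 30-day females (adjusted p = 1.19e-09) and -4.00 ± 0.27 in 30-day males (adjusted p = 1.52e-10). They were -3.43 ± 0.26 in 60-day females (adjusted p = 2.69e-09) and -2.96 ± 0.25 in 60-day males (adjusted p = 5.89e-08).

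**Figure D1:**
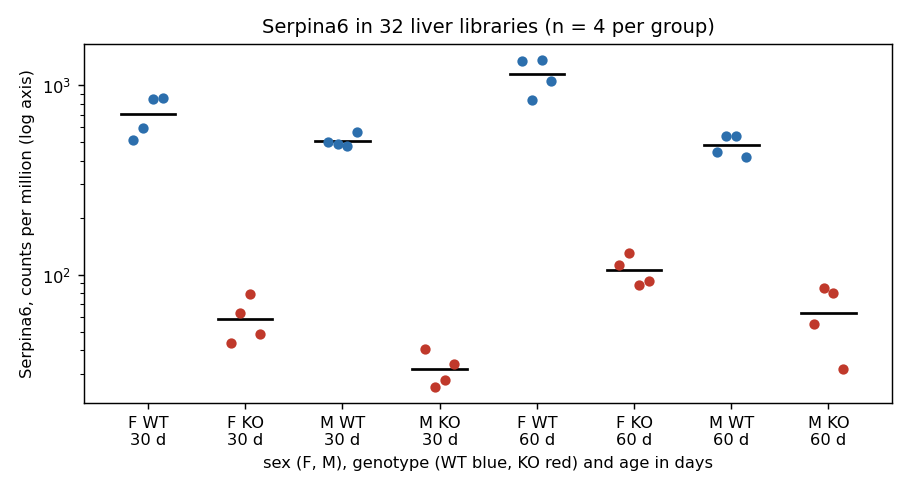
Serpina6 in CPM (log axis) for each of the 32 liver libraries, by sex (F, M), genotype (WT blue, KO red) and age in days; each point is 1 library and each bar the mean of 4. In every stratum the 4 KO points lie below the 4 WT points, for example at most 131 against at least 835 CPM in 60-day females.

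In 60-day KO females 15 of 25 genes of cholesterol synthesis, 9 of 23 acute phase genes, 4 of 14 genes of pericentral hepatocytes and 8 of 19 genes of endoplasmic reticulum stress fell, and of 15 clock genes 4 rose and 1 fell. In the same order the first 4 lists had adjusted p = 0.128, 0.0372, 0.0372 and 0.197 with an estimated correlation, and the clock list had camera adjusted p = 0.219. With 1 of the 8 libraries left out in turn, the estimated-correlation call of the acute phase list held in 3 fits and that of the pericentral list in 2. Pfkfb1, which encodes the liver form of the enzyme that makes and breaks fructose 2,6-bisphosphate, fell by 2.68 ± 0.27 to 2.06 ± 0.957 CPM from 13.1 ± 4.59 CPM (adjusted p = 4.35e-07). Cyp3a9, a steroid hydroxylase of the female-biased list, fell by 2.29 ± 0.30 to 87.4 ± 32.2 from 426 ± 83.8 CPM (adjusted p = 3.95e-05). Saa4, a serum amyloid A apolipoprotein, fell by 1.07 ± 0.13 (adjusted p = 9.77e-06), and Hmgcs1, which makes the precursor of mevalonate, by 1.75 ± 0.24 (adjusted p = 6.15e-05). By edgeR's test 745 genes changed, 383 higher and 362 lower, and 207 of them by a log2 fold change of at least 1 in size. The count was 277 in a fit to the 16 libraries of that age (266 of them among the 745) and 56 in a fit to the 8 libraries compared (51 among them). It was 132 with a clock score, chosen after the data were seen, as a covariate, where the fold changes of the 745 kept a share of 0.607 and their SE grew 1.30 times. Such a share is a slope through the origin over the called genes, Serpina6 included where called, so the largest fold changes weigh most.

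Of 25 measured genes of cholesterol synthesis, 15 fell and 0 rose over all genes tested, and 19 fell when adjusted over the list alone. Hmgcs1 was joined by Idi1, the isopentenyl diphosphate isomerase (-1.89 ± 0.33), by Cyp51, the lanosterol demethylase (-1.15 ± 0.18), and by Fdft1, squalene synthase (-0.75 ± 0.14). The list's median fold change was -0.71, with camera adjusted p = 3.12e-19 at the preset correlation and adjusted p = 0.128 with an estimated correlation. Srebf1, a transcription factor of lipid synthesis, rose by 1.35 ± 0.21 and was the 1 member of 19 on the fatty acid synthesis list to change (2 higher and 1 lower adjusted over the list alone). Camera gave it adjusted p = 0.00324, and adjusted p = 0.54 with an estimated correlation. Of 23 acute phase genes 9 fell and 0 rose (14 lower adjusted over the list alone). By camera the list had adjusted p = 1.5e-09, and adjusted p = 0.0372 with an estimated correlation. They included Orm1, alpha-1-acid glycoprotein (-1.88 ± 0.29), Itih3 (-0.41 ± 0.08) and Fgg, the fibrinogen gamma chain (-0.37 ± 0.09). Of 14 genes of pericentral hepatocytes 4 fell and 0 rose (9 lower adjusted over the list alone). Its camera adjusted p was 6.46e-07, and adjusted p = 0.0372 with an estimated correlation. The 4 were Slc1a2, a glutamate transporter (-2.34 ± 0.33), Cyp1a2, an inducible monooxygenase (-1.09 ± 0.17), Gulo, which makes vitamin C in rodents (-0.66 ± 0.15), and Glul, glutamine synthetase (-0.65 ± 0.16). Of 19 genes of endoplasmic reticulum stress 8 fell and 0 rose (1 higher and 12 lower adjusted over the list alone). For the list, camera gave adjusted p = 1.08e-07, and adjusted p = 0.197 with an estimated correlation. The examples were Sdf2l1 (-1.01 ± 0.20), the secreted survival factor Manf (-0.62 ± 0.15), the transcription factor Xbp1 (-0.47 ± 0.12) and the chaperone Hyou1 (-0.73 ± 0.18). Without replicate 4 of the WT females the adjusted p of Glul was 0.0816, of Manf 0.0658 and of Hyou1 0.091.

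Among 26 targets of the glucocorticoid receptor 4 fell and 0 rose in 60-day KO females (1 higher and 5 lower adjusted over the list alone). Tested by camera, it had adjusted p = 0.00981, and adjusted p = 0.206 with an estimated correlation. They were Zbtb16 (-1.93 ± 0.37), Pck1, the key enzyme of gluconeogenesis (-1.497 ± 0.329), Klf9 (-0.73 ± 0.22) and Glul, while Nr3c1, the receptor itself, was at -0.02 ± 0.12 and did not pass the test. The clock list had 4 members higher and 1 lower of 15, with the same counts adjusted over the list alone (camera adjusted p = 0.219). Per3 rose by 1.80 ± 0.31, Per2 by 1.60 ± 0.28, Dbp by 2.27 ± 0.45 and Tef by 0.94 ± 0.18, all of them clock-controlled genes. Among 28 genes of xenobiotic metabolism 3 rose and 6 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.0534). Ephx1, microsomal epoxide hydrolase, rose by 1.27 ± 0.26, and Nr1i3, the receptor CAR, fell by 2.29 ± 0.52. Of 24 targets of PPAR-alpha 6 rose and 1 fell (9 and 1 adjusted over the list alone). Tested by camera, it had adjusted p = 0.0116, and adjusted p = 0.54 with an estimated correlation. Among them were Acadm (0.37 ± 0.06), a dehydrogenase of fatty acid oxidation, and the fatty acid binding protein Fabp1 (0.51 ± 0.14). Of 18 bile acid genes 1 rose and 3 fell (2 and 5 adjusted over the list alone). Camera gave it adjusted p = 0.0215, and adjusted p = 0.326 with an estimated correlation. Abcb4, the phospholipid exporter of bile, fell by 0.68 ± 0.10, and the uptake carrier Slco1a1 rose by 0.33 ± 0.08. Gluconeogenesis and glycolysis had 0 of 22 higher and 3 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.538), namely Pfkfb1, Pck1 and the transaminase Gpt (-1.08 ± 0.26). The urea cycle list had 1 of 24 higher and 2 lower (1 and 4 adjusted over the list alone; camera adjusted p = 0.18), with Ass1, argininosuccinate synthase, at -0.59 ± 0.14. With 1 WT female left out, the adjusted p of Klf9 was 0.163 (replicate 3), of Gpt 0.0545 and of Fabp1 0.0983 (replicate 2), and of Glul 0.0816, of Nr1i3 0.0593 and of Slco1a1 0.0547 (replicate 4).

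The lists of sex-biased genes had few members past the threshold in 60-day KO females. Of 22 male-biased genes 2 rose and 0 fell, Slco1a1 and Car3 (1.34 ± 0.40), with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.551). Of 13 female-biased genes 1 rose, the sulfotransferase Sult2a2 (5.97 ± 1.20), and 1 fell, Cyp3a9 (1 and 2 adjusted over the list alone; camera adjusted p = 0.0514). Cyp2c12, the main female-specific monooxygenase, was at -0.27 ± 0.26, and Ghr, the growth hormone receptor, at 0.11 ± 0.12. Igf1 was at -0.02 ± 0.12 and Hsd11b1, which regenerates corticosterone, at 0.00 ± 0.34. None of the 4 passed the test. Steroid binding and metabolism had 1 of 20 higher and 2 lower, Serpina6 among them, and growth hormone signalling 0 of 21 (camera adjusted p = 0.272 and 0.28). Adjusted over the list alone these became 1 higher and 2 lower, and 1 higher and 3 lower. The interferon list had 2 of 25 higher, Ifit2 and Rsad2, and 0 lower (4 higher adjusted over the list alone). By camera the list had adjusted p = 0.00424, and adjusted p = 0.566 with an estimated correlation. The cell cycle list had 1 of 28 higher, Bub1b, and 0 in the count adjusted over the list alone (camera adjusted p = 0.000347, and adjusted p = 0.54 with an estimated correlation). The adjusted p of Car3 was 0.148 without replicate 2 and of Bub1b 0.284 without replicate 1 of the KO females. That of Ifit2 was 0.0587 without replicate 2, and of Rsad2 0.129 and of Slco1a1 0.0547 without replicate 4 of the WT females.

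Few markers of other cells passed the test in 60-day females. Sparc, a matrix protein, rose by 0.52 ± 0.10 and was 1 of 15 stellate and fibroblast genes to change, and Epcam rose by 0.54 ± 0.12 as 1 of 8 cholangiocyte genes. Of Kupffer cell genes 0 of 15 changed by edgeR's test, of lymphocyte genes 0 of 13 and of neutrophil genes 0 of 5. Of endothelial genes 0 of 15 and of the handling list (immediate early and heat shock genes) 0 of 16 changed by the same test, and the 5 lists had camera adjusted p between 0.0534 and 0.756. Fetal genes had 1 of 9 higher, periportal genes 2 of 13 higher and 2 lower, and the list of pancreas, adipose tissue and muscle 1 of 4 higher, Cela1, and 1 lower, Cpa1 (camera adjusted p = 0.193, 0.701 and 0.701). Adjusted over the list alone, 1 stellate, 1 cholangiocyte, 2 neutrophil and 1 fetal gene were higher. On that basis 3 periportal genes were higher and 3 lower, 1 of the 4 tissue markers was higher and 1 lower, and 0 changed on the Kupffer, lymphocyte, endothelial and handling lists. The erythroid list had 0 of 11 changed by edgeR's test, with all 11 fold changes positive (camera adjusted p = 0.00901, and adjusted p = 0.54 with an estimated correlation). The adjusted p of Cela1 was 0.0829 without replicate 1 of the KO females, and of Cpa1 0.0939 without replicate 3 of the WT females.

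Replicate 1 of the 60-day KO females held transcripts of photoreceptors: on a retina list chosen after the values were seen, 24 of 24 measured genes had their highest level there, summed to 2375 CPM, against 6.1 to 13.8 CPM in the other 3 KO females. The higher genes with the largest fold changes included Rp1 (10.2 ± 20.1 CPM in KO and 0.0163 ± 0.0326 in WT), Ndrg4 (3.27 ± 0.78), Abca4, Ntm, Fndc1 and Aqp4. Without that library the adjusted p of Rp1 was 0.412, of Ndrg4 0.516, of Ntm 0.0624, of Fndc1 0.126 and of Aqp4 0.419, while Abca4 kept its call. Hdc, the histamine-forming enzyme (2.69 ± 0.47), and the lower genes Scube1 (-2.34 ± 0.46), Slc1a2 and Pfkfb1 passed the test in each fit that left out 1 library. The count was 399 genes without that library, and 733, 667 and 669 without replicates 2, 3 and 4 of the KO females. It was 978, 435, 541 and 412 without replicates 1, 2, 3 and 4 of the WT females. In all 8 such fits 33 of the 64 named genes past the threshold, Serpina6 not counted, kept their call.

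**Figure D2:**
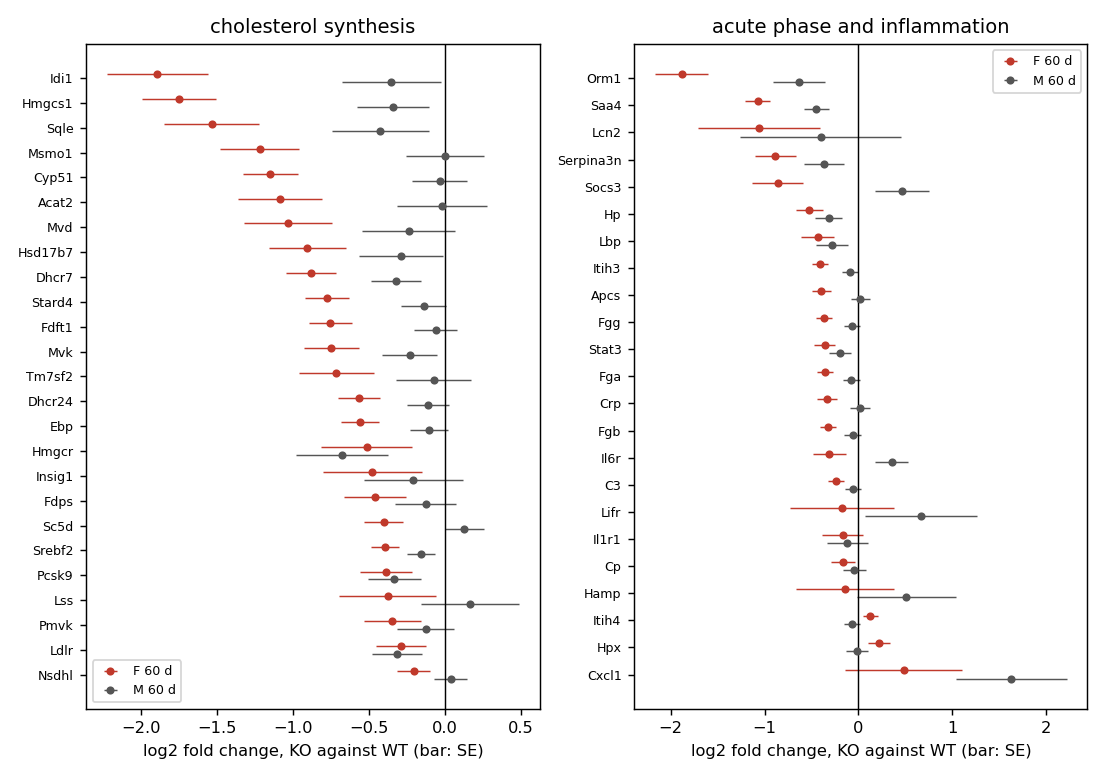
Log2 fold change (KO against WT, bars ± SE, n = 4 per group) of each measured gene of the cholesterol synthesis list (left) and the acute phase list (right), in 60-day females (red) and 60-day males (grey). In females all 25 cholesterol genes lie below 0 and 15 passed the test, as did 9 of the 23 acute phase genes, all lower; in males 0 genes of either list passed edgeR's test.

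At 30 days, KO females differed from WT females in few genes, led by a neighbour of the target. Serpina5, the protein C inhibitor and a close neighbour of Serpina6, rose by 2.63 ± 0.42 to 4.43 ± 1.33 from 0.714 ± 0.497 CPM (adjusted p = 0.00286). Fos, an immediate early gene, fell by 2.58 ± 0.55 and was the 1 member of 16 on the handling list to change (5 lower adjusted over the list alone; camera adjusted p = 0.000834, and adjusted p = 0.259 with an estimated correlation). Genes that fell also included Igfbp6 (-2.27 ± 0.51), and Cyp1a1, a monooxygenase (-2.21 ± 0.43). Also lower were Cyp11a1, the side-chain cleavage enzyme of steroid synthesis (-2.77 ± 0.56, at 0.174 against 1.25 CPM), Col1a1, type I collagen (-1.30 ± 0.26), and Xbp1 (-0.54 ± 0.12). Genes that rose included Rragd (1.75 ± 0.34), Rtp4 (1.501 ± 0.298), Mfsd1 (1.19 ± 0.26), Pls1 (0.75 ± 0.14), Cep70 (0.68 ± 0.15) and Cyb561a3 (0.60 ± 0.13). Sema3e (-1.75 ± 0.39) and Aoc3 (-1.42 ± 0.29) were lower as well. In all 33 genes changed, 13 higher and 20 lower. All 4 KO females carried the number 2 after the hyphen of their title and 3 of the 4 WT females the number 1. In the fit to the 16 libraries of that age 8 genes changed with that number as a covariate, against 50 without it. Of the 8, 4 were among the 33, and the adjusted p of Serpina5 was 0.0579 with the covariate. With the clock score as a covariate 3 genes changed, all among the 33, while the fold changes of the 33 kept a share of 0.981 and their SE grew 1.15 times. The median size of these fold changes went from 1.191 to 1.063. Fits to the 16 libraries of that age and to the 8 compared called 50 and 8, with 19 and 4 of the 33 among them. Upper-quartile scaling left 26.1% of the calls higher and the authors' deposited log2 values left 80%, against 39.4% here. Cell cycle genes had 0 of 28 changed over all genes by edgeR's test and 10 lower adjusted over the list alone (median -0.51, camera adjusted p = 2.88e-15, and adjusted p = 0.259 with an estimated correlation). Of 15 stellate genes 1 fell, Col1a1, and 10 when adjusted over the list alone (camera adjusted p = 3.97e-11, and adjusted p = 0.0668 with an estimated correlation). The 25 cholesterol genes all had positive fold changes with 0 past the threshold (median 0.36, camera adjusted p = 4.05e-08, and adjusted p = 0.373 with an estimated correlation). Of the 25 interferon genes 23 were positive, 0 past it and 1 adjusted over the list alone (camera adjusted p = 2.32e-09, and adjusted p = 0.329 with an estimated correlation). PPAR-alpha, fetal, erythroid and lymphocyte genes also passed camera (adjusted p = 0.000834, 0.00368, 0.00966 and 0.0449, and 0.329, 0.167, 0.592 and 0.592 with an estimated correlation). In this contrast 1175 genes had an unadjusted p below 0.05, and DESeq2 called 92 and limma-voom 38 genes. Leaving out 1 library gave between 4 genes (without replicate 2 of the KO females) and 60 (without replicate 4 of the WT females), and of the 16 named genes other than Serpina6 only Serpina5 kept its call in all 8 fits. Without replicate 1 of the WT females the adjusted p of Rtp4 and of Pls1 was 0.0993, of Col1a1 0.135, of Cyp11a1 0.175, of Sema3e 0.203 and of Fos 0.219. Without replicate 1 of the KO females that of Cyp1a1 was 0.0911, of Aoc3 0.101, of Mfsd1 and of Xbp1 0.118, of Rragd 0.147 and of Igfbp6 0.205. That of Cep70 was 0.162 without replicate 4 of the KO females, and that of Cyb561a3 0.189 without replicate 2 of the WT females.

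In males edgeR's test called 6 genes between KO and WT livers at 30 days and 23 at 60 days. At 60 days 2 of 35 splits of the libraries called as many, the real one included. The highest other called 55, so chance cannot be excluded for the 23. At 30 days Mast3, a kinase (0.91 ± 0.16), Tmem135 (0.79 ± 0.14) and the filament protein Synm (0.71 ± 0.14) rose, while Serpina6, Bcl10 (-0.50 ± 0.10) and Klkb1, plasma prekallikrein (-0.40 ± 0.07), fell. At 60 days Cebpb, a transcription factor of the acute phase and of gluconeogenesis, fell by 1.01 ± 0.17 to 37.4 ± 6.77 from 75.2 ± 6.96 CPM (adjusted p = 0.00792). Apoa4, an apolipoprotein (-1.46 ± 0.30), Nnmt, nicotinamide methyltransferase (-1.22 ± 0.23), the transcription factors Atf3 (-1.82 ± 0.38) and Jund (-0.93 ± 0.18), Scand1 (-0.70 ± 0.15), Prkab1 (-0.64 ± 0.14) and Bri3 (-0.48 ± 0.10) also fell. Kcnj3, a potassium channel (2.88 ± 0.49, at 1.42 against 0.194 CPM), Pkib (1.67 ± 0.30), Rin2 (0.90 ± 0.19), Dapk1 (0.75 ± 0.15) and Tbc1d2b (0.44 ± 0.09) rose. Of 26 glucocorticoid receptor targets 1 fell at 60 days, Cebpb, and 2 when adjusted over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.133 with an estimated correlation). Gluconeogenesis and the urea cycle had 0 of 22 and 0 of 24 changed over all genes by edgeR's test and 2 lower each adjusted over the list alone (camera adjusted p = 0.00079 for both, and adjusted p = 0.133 and 0.854 with an estimated correlation). In the same contrast 12 of 15 stellate genes had positive fold changes, 0 past edgeR's test over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000868, and adjusted p = 0.662 with an estimated correlation). So had 11 of 13 lymphocyte and 25 of 28 cell cycle genes, 0 past it in either count (camera adjusted p = 0.0209 and 0.0119, and adjusted p = 0.854 for both with an estimated correlation). At 30 days all 24 urea cycle genes had negative fold changes with 0 past the threshold in either count (camera adjusted p = 7.71e-09, and adjusted p = 0.43 with an estimated correlation). At that age 18 of 22 male-biased genes were negative, with 1 lower adjusted over the list alone (camera adjusted p = 0.00996, and adjusted p = 0.804 with an estimated correlation). Cholesterol synthesis, interferon and steroid genes also passed camera at 30 days (adjusted p = 7.45e-08, 3.72e-05 and 0.00571, and 0.804, 0.804 and 0.395 with an estimated correlation). So did periportal, fatty acid synthesis, endothelial and handling genes (adjusted p = 0.00735, 0.00996, 0.0298 and 0.0457, and 0.804, 0.858, 0.858 and 0.804 with an estimated correlation). Cyp2c11, the main male-specific monooxygenase, was at -0.30 ± 0.45 at 30 days and -0.13 ± 0.45 at 60 days and passed the test at neither age. At 30 days 653 and at 60 days 1188 genes had an unadjusted p below 0.05, and DESeq2 called 26 and 65. With the clock score as a covariate 2 genes changed at 30 days and 19 at 60 days, while fold changes of the called genes kept shares of 1.04 and 1.01 and their SE grew 1.05 and 1.02 times. Serpina6, which the knockout itself fixes, dominates the 30-day share. The median size of the fold changes went from 0.75 to 0.689 at 30 days and from 0.699 to 0.688 at 60 days. At 30 days a fit to the 8 libraries compared called 5 genes, 1 of them among the 6. The fit to the 16 libraries of that age called 16, and 8 with the title number as a covariate, 3 of these 8 among the 6. Leaving out 1 library gave 1 (without replicate 3 of the KO males) to 7 genes at 30 days. At 60 days it gave 2 (without replicate 1 of the KO males, where Cebpb was at adjusted p = 0.0614) to 46 (without replicate 4 of the KO males). The authors' deposited log2 table gave 4 at 60 days, and so did a fit to the 16 libraries of that age, all 4 among the 23. A fit to the 8 compared called 8, with 5 of the 23 among them. At 30 days the adjusted p of Mast3 was 0.061 without replicate 3 and of Bcl10 0.179 and of Synm 0.214 without replicate 1 of the KO males. That of Tmem135 was 0.0987 without replicate 1 and that of Klkb1 0.0926 without replicate 4 of the WT males. At 60 days that of Kcnj3 and of Pkib was 0.0644 and of Scand1 0.133 without replicate 1 of the KO males. That of Apoa4 and of Bri3 was 0.142, of Dapk1 0.142, of Rin2 0.179 and of Prkab1 0.18 without replicate 3 of the KO males. That of Nnmt was 0.0948, of Tbc1d2b 0.147, of Jund 0.153 and of Atf3 0.176 without replicate 3 of the WT males.

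The difference of the KO effect between the sexes was tested as an interaction. At 30 days edgeR's test called 0 genes, with 606 at an unadjusted p below 0.05, and DESeq2 and limma-voom also called 0, with 618 and 703. The handling list had 0 of 16 past edgeR's test in either count, with 14 of the 16 more positive in males (camera adjusted p = 4.57e-06, and adjusted p = 0.137 with an estimated correlation). All 28 cell cycle genes were more positive in males with 0 past edgeR's test in either count (camera adjusted p = 6.02e-11, and adjusted p = 0.463 with an estimated correlation). So were 13 of 15 stellate genes, 0 past it over all genes and 2 adjusted over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 0.137 with an estimated correlation). Of 15 endothelial genes 14 were more positive, 0 past it in either count (camera adjusted p = 0.0272, and adjusted p = 0.908 with an estimated correlation). At 60 days 15 genes differed, 11 with a more positive and 4 with a more negative KO effect in males. A fit to the 16 libraries of that age called 2 of them, and 10 of 100 splits of the libraries called as many as 15, so chance cannot be excluded for this count. With the clock score as a covariate 4 genes differed, while the fold changes of the 15 kept a share of 0.937 and their SE grew 1.09 times. Pfkfb1 led them (2.62 ± 0.35, adjusted p = 0.000371): it stood at 27.91 and 28.97 CPM in KO and WT males, and at 2.06 and 13.1 CPM in KO and WT females. Abcb4 (0.93 ± 0.14) and Nudt4 (0.70 ± 0.12) also kept their call in each fit with 1 library left out. Popdc2 (2.81 ± 0.54), Pm20d2 (1.68 ± 0.36), Serpina3c (1.03 ± 0.19), Dirc2 (0.79 ± 0.16) and Tti1 (0.69 ± 0.15) were more positive in males. The sorting receptor Sorl1 (-1.53 ± 0.29), the corepressor Tle3 (-1.24 ± 0.23) and Paqr7, a membrane progestin receptor (-1.01 ± 0.19), were more negative. Of the cholesterol list 0 of 25 genes passed edgeR's test over all genes and 10 were more positive in males adjusted over the list alone (camera adjusted p = 5.59e-11, and adjusted p = 0.376 with an estimated correlation). Pericentral genes had 0 of 14 over all genes by edgeR's test and 5 adjusted over the list alone (camera adjusted p = 1.47e-06, and adjusted p = 0.0772 with an estimated correlation). Of 13 female-biased genes 12 were more positive in males, 0 past edgeR's test over all genes and 3 adjusted over the list alone (camera adjusted p = 0.000718, and adjusted p = 0.432 with an estimated correlation). Acute phase genes were more positive in 21 of 23 cases and endoplasmic reticulum stress genes in 15 of 19, with 0 past it over all genes and 6 each adjusted over the list alone. Camera gave them adjusted p = 1.88e-06 and 1.85e-05, and adjusted p = 0.137 and 0.376 with an estimated correlation. Among other cells 13 of 15 Kupffer genes were more positive and all 11 erythroid genes more negative, 0 past it in either count (camera adjusted p = 0.0105 and 0.0104, and adjusted p = 0.688 for both with an estimated correlation). PPAR-alpha targets were more negative in 19 of 24 cases, fatty acid synthesis genes in 15 of 19 and interferon genes in 23 of 25, with 0 past it over all genes and 4, 1 and 0 adjusted over the list alone. Camera gave them adjusted p = 0.00832, 0.033 and 0.0428, and adjusted p = 0.483, 0.688 and 0.817 with an estimated correlation. DESeq2 called 94 genes (54.3% more positive against 73.3% here), the authors' deposited log2 table left 52.4% more positive, and the count was 5 without replicate 3 and 126 without replicate 1 of the WT females. Without replicate 3 of the WT females the adjusted p of Serpina3c, of Tle3 and of Paqr7 was 0.0537, and of Dirc2 and of Sorl1 0.069. That of Tti1 was 0.108 without replicate 2 of the WT females, of Popdc2 0.0859 without replicate 1 of the KO males and of Pm20d2 0.121 without replicate 3 of the WT males.

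The sex difference itself was large at 60 days and smaller at 30 days. In WT liver 2901 genes differed between the sexes at 60 days, 1503 higher and 1398 lower in males, against 228 (119 and 109) at 30 days. At 60 days Cyp2c11 stood at 2007 ± 493 CPM in males and 0.441 ± 0.352 in females, and Cyp2c12 at 62.5 ± 19.0 in males and 4988 ± 336 in females (fold changes 12.11 ± 0.80 and -6.32 ± 0.32). Cyp2c13 (10.15 ± 0.62), Cyp2a2 (10.58 ± 0.60), Cyp3a2 (10.10 ± 0.49) and Cyp4a2 (5.47 ± 0.25), further monooxygenases, and Hao2 (4.00 ± 0.22) were higher in males. The urinary protein gene Mup5 was at 502 ± 105 CPM in males and 0.0336 ± 0.0672 in females. The carrier Slc22a8 was at 261 ± 48.0 and 0.0360 ± 0.0418, and Hsd3b5, a steroid dehydrogenase, at 206 ± 11.9 in males with 0 reads in every WT female. On the female side, A1bg (0.586 ± 0.304 CPM in males against 6301 ± 1307) and Akr1b7 (0.0487 ± 0.0632 against 699 ± 127) were higher. So were the leukaemia inhibitory factor receptor Lifr (-7.17 ± 0.73), the prolactin receptor Prlr (-5.13 ± 0.76), Cux2, a repressor of male-biased genes (-6.51 ± 0.63), Trim24 (-5.25 ± 0.45) and Srd5a1, steroid 5-alpha reductase (-2.60 ± 0.26). Hsd11b1 was higher in males by 4.99 ± 0.39, and Igf1 by 0.61 ± 0.12, while Ghr (-0.54 ± 0.12) and Serpina6 (-1.24 ± 0.24) were higher in females. Nr3c1 was higher in males by 0.36 ± 0.12, with adjusted p = 0.0183, and 0.11 without replicate 4 of the WT males.

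Of the male-biased list 19 of 22 genes were higher in WT males at 60 days and 0 lower (20 adjusted over the list alone). Camera gave it adjusted p = 2.86e-24, and adjusted p = 0.00235 with an estimated correlation. Of the female-biased list 11 of 13 were lower and 0 higher (11 adjusted over the list alone). Its camera adjusted p was 4.45e-14, and adjusted p = 0.0126 with an estimated correlation. Cholesterol synthesis had 19 of 25 genes lower in males and 0 higher (19 adjusted over the list alone; camera adjusted p = 3.81e-10, and adjusted p = 0.291 with an estimated correlation), led by Tm7sf2 (-2.06 ± 0.25) and Cyp51 (-1.39 ± 0.18). Pericentral genes had 10 of 14 lower in males and 1 higher (10 and 1 adjusted over the list alone). By camera the list had adjusted p = 4.05e-05, and adjusted p = 0.0935 with an estimated correlation. Cyp2e1 was at -1.70 ± 0.23, Cyp1a2 at -1.49 ± 0.17 and Slc1a2 at -2.69 ± 0.34. Of the genes on sex chromosomes, 1 was in the files, the Y-linked helicase Ddx3y (1.34 ± 0.49, adjusted p = 0.0404, and 0.152 without replicate 3 of the WT females). So small a difference, lost without 1 library, does not serve as a check of the sex labels. At 30 days the male-biased list already had 13 of 22 genes higher in WT males (16 adjusted over the list alone). Its camera adjusted p was 1.12e-24, and adjusted p = 0.00211 with an estimated correlation. Cyp2c13 was at 8.41 ± 0.57, Cyp2c11 at 5.70 ± 0.57, Cyp2a2 at 5.38 ± 0.44, Rdh16 at 4.30 ± 0.49, Nox4 at 4.37 ± 0.70 and the repressor Bcl6 at 3.69 ± 0.68. The female-biased list had 7 of 13 lower in males (8 adjusted over the list alone). For the list, camera gave adjusted p = 1.79e-09, and adjusted p = 0.041 with an estimated correlation. Cux2 was at -5.09 ± 0.58, Akr1b7, outside the list, at -5.74 ± 0.49, and Cyp2c12 at -1.15 ± 0.26 (adjusted p = 0.0703 without replicate 4 of the WT females). Leaving out 1 library at 30 days gave at the fewest 119 genes, without replicate 3 of the WT females.

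In KO liver 2037 genes differed between the sexes at 60 days (1059 higher and 978 lower in males) and 246 at 30 days (94 and 152). Cyp2c11 was at 1833 ± 717 CPM in KO males and 0.110 ± 0.146 in KO females, with Cyp2c12 at 82.3 ± 23.6 and 4129 ± 254 and Cyp2c13 at 1959 ± 537 and 0.506 ± 0.235. In the same order Mup5 was at 450 ± 101 and 0.0461 ± 0.0922 and A1bg at 7.09 ± 9.25 and 6380 ± 1360. Hsd11b1 was higher in males by 4.44 ± 0.38 and Igf1 by 0.88 ± 0.12, and Ghr was lower (-0.56 ± 0.12). Of the male-biased list 20 of 22 genes were higher in KO males at 60 days (22 adjusted over the list alone). Tested by camera, it had adjusted p = 5.22e-33, and adjusted p = 0.000297 with an estimated correlation. Of the female-biased list 11 of 13 were lower and 1 higher (11 and 1 adjusted over the list alone). For the list, camera gave adjusted p = 1.54e-13, and adjusted p = 0.0183 with an estimated correlation. At 30 days the same lists had 8 of 22 higher and 6 of 13 lower (13 and 9 adjusted over the list alone; adjusted p = 0.0108 and 0.0327 with an estimated correlation). The authors' deposited log2 table left 48.4% of the 30-day calls higher in males against 38.2% here. At that age all 4 KO females carried the number 2 after the hyphen of their title and 3 of the 4 KO males the number 1. In the fit to the 16 libraries of that age 110 genes differed with that number as a covariate, against 401 without it. Of the 110, 62 were higher and 48 lower in males (56.4% higher), and 34.6% of the 246 calls were kept. Fits to the 16 libraries of that age and to the 8 compared called 401 and 461, with 214 and 213 of the 246 among them. At 60 days 1062 genes differed with the clock score as a covariate, 983 of them among the 2037, while the fold changes of the 2037 kept a share of 0.864 and their SE grew 1.29 times. Leaving out 1 library at 30 days gave at the fewest 124 genes, without replicate 2 of the KO males. The smaller count in KO than in WT at 60 days is not by itself a test of a difference, which was the interaction above.

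**Figure D3:**
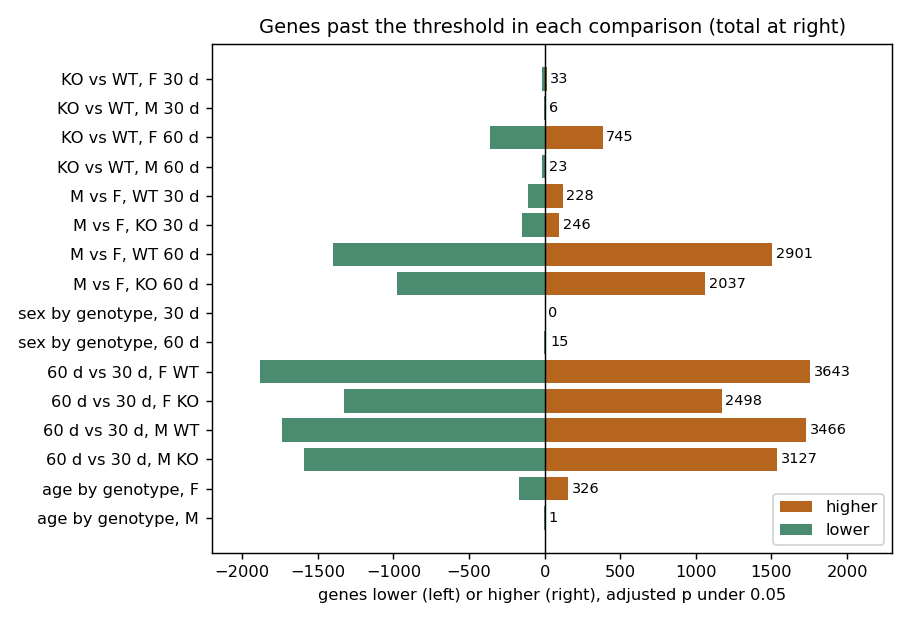
Number of genes past the threshold (adjusted p below 0.05 of 11002 genes tested) in each of the 16 comparisons, higher to the right and lower to the left of 0, with the total beside each bar. For KO against WT more genes passed in 60-day females (745) than in 30-day females (33), 30-day males (6) and 60-day males (23). Fits to the 8 libraries compared called 56, 8, 5 and 8 in the same order. Such counts are not a test of a difference of the KO effect, which the interactions were. The age comparisons hold 2498 to 3643 genes.

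A sex score, the mean log2 CPM of the male-biased list minus that of the female-biased list, summarised the sex bias of each library. Its mean was -7.03 ± 0.11 (SD, n = 4) in WT females and 2.98 ± 0.50 in WT males at 60 days, and -6.90 ± 0.28 in KO females and 2.57 ± 1.20 in KO males. At 30 days it was -4.06 ± 0.84 and -0.42 ± 0.36 in WT, and -4.18 ± 0.64 and -0.75 ± 0.46 in KO females and males. The sexes differed by 10.01 in WT and 9.47 in KO at 60 days and by 3.64 and 3.43 at 30 days, each with two-sided exact permutation p = 0.0286, the smallest that 70 arrangements of 4 against 4 allow. KO minus WT was -0.11 and -0.33 in females and males at 30 days and 0.13 and -0.41 at 60 days (two-sided exact permutation p = 0.8, 0.2, 0.4 and 0.629). Adjusted by Benjamini-Hochberg each of the 4 was 0.8, and none passed the test. The KO effect on the score differed between the sexes by -0.21 at 30 days and -0.54 at 60 days (two-sided exact permutation within sex, 4900 arrangements, p = 0.722 and 0.418).

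**Figure D4:**
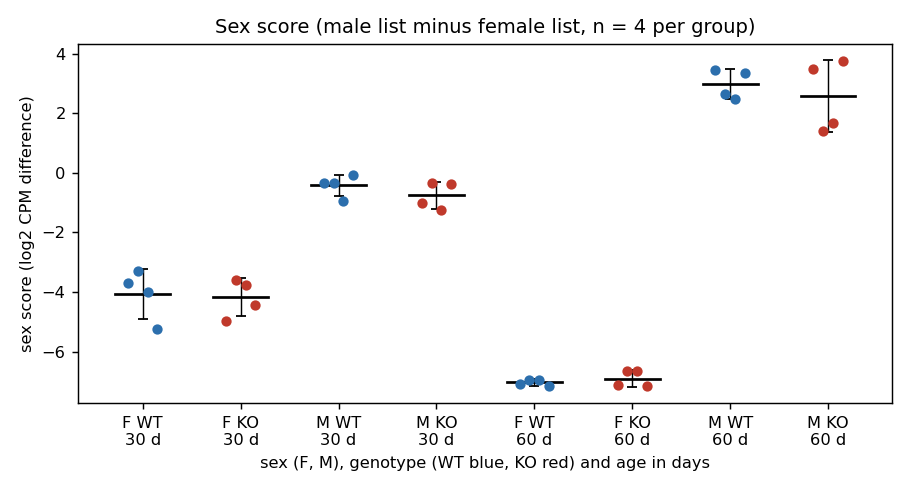
Sex score (log2 CPM, mean of the male-biased list minus mean of the female-biased list) of each of the 32 libraries by sex, genotype (WT blue, KO red) and age; points are libraries, bars the mean ± SD of 4. At 60 days females lie between -7.16 and -6.65 and males between 1.42 and 3.74, and KO and WT overlap in each stratum.

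Whether genes changed by the knockout moved toward the other sex was asked for 60-day liver with sex bias called in WT libraries that the KO contrast did not use. Each of 6 choices of 2 WT males called the sex bias and the other 2 were compared with the KO males, and over these choices 10 calls were also sex-biased, of which 3 (30%) moved toward females. Serpina6, whose direction the knockout itself fixed, was 1 of the calls in each of the 6 choices. Without it, as counted after the data were seen, 4 calls were left, Jund, Prkab1, Pcdh18 and Tanc1, with 3 toward females, too few to give a share. For females, an extension chosen after the data were seen, 283 of 377 such calls (75.1%, between 67.2% and 84% over the 6 choices) moved toward males, and 277 of 371 without Serpina6. These calls are summed over the 6 choices, which share libraries, so 1 gene can count up to 6 times. With all 4 WT libraries in both contrasts the shares were 333 of 390 genes (85.4%) in females and 13 of 18 (72.2%) in males, and 332 of 389 and 13 of 17 without Serpina6. The shared WT libraries alone move genes this way. In simulations all 60-day libraries, WT included, were redrawn from the fitted model with KO set equal to WT. They put 61.4% (59.5% to 62.8% over 20 simulations) of all sex-biased genes toward males and 61.5% (59.4% to 63.4%) toward females. The observed shares were 69.8% and 68.1% with shared WT libraries in the fit to all 32 libraries. They were 57.8% to 64.8% and 52.3% to 61.5% over the 6 choices with the WT libraries divided. The simulations drew each gene independently, used a fit to the 60-day libraries alone and were not run with divided WT libraries. Their range is therefore no test of the observed shares. A sex score of the genes so called was higher in KO than in WT females by 0.34 to 0.45 over the 6 choices, Serpina6 left out, where the smallest two-sided exact permutation p that 4 against 2 libraries allow, 0.0667, was reached each time and none could pass the test. In males the KO difference of that score lay between -0.35 and 0.00 (two-sided exact permutation p = 0.2 to 0.933).

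Between 30 and 60 days most genes of the cell cycle list fell in every group, while 10 of 13 female-biased genes rose in WT females and 13 of 22 male-biased genes in WT males. In WT females 3643 genes changed (1758 higher, 1885 lower), in KO females 2498 (1171 and 1327), in WT males 3466 (1727 and 1739) and in KO males 3127 (1537 and 1590). H19, an imprinted fetal transcript, fell by 9.86 ± 0.85 in WT females to 0.583 ± 0.395 from 539 ± 411 CPM. It fell by 7.52 ± 0.75 in WT males, by 6.81 ± 0.75 in KO females and by 7.37 ± 0.74 in KO males. All 28 cell cycle genes fell in WT females and 27 of 28 in each other group. Examples were Top2a, topoisomerase II (-5.23 ± 0.37), Nusap1 (-5.23 ± 0.36) and Tk1, thymidine kinase (-2.58 ± 0.16), in WT females and Aurkb, a mitotic kinase (-4.69 ± 0.39), in WT males. Camera gave the list adjusted p = 3.45e-23, 4e-22, 3.72e-24 and 2.58e-23 in WT females, KO females, WT males and KO males, and adjusted p = 0.193, 0.195, 0.127 and 0.138 with an estimated correlation. Stellate genes fell in WT females, 13 of 15 with 1 higher (camera adjusted p = 7.53e-09, and adjusted p = 0.168 with an estimated correlation). Among them were Col1a1 (-3.17 ± 0.29), Col3a1 (-2.04 ± 0.17), Col5a1 (-1.75 ± 0.13) and Sparc (-1.58 ± 0.10). Adjusted over the list alone, 28 cell cycle and 13 stellate genes fell in WT females.

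In WT females Cyp3a9 rose by 9.88 ± 0.48 to 426 ± 83.8 CPM. Lifr rose by 5.74 ± 0.68, Cyp2c7 by 2.82 ± 0.55, Ghr by 1.04 ± 0.12 and Hal, histidine ammonia-lyase, by 2.07 ± 0.23. Among male-biased genes Cyp3a2 (-8.56 ± 0.47) and Car3 (-2.99 ± 0.42) fell, as did Hsd11b1 (-4.46 ± 0.38). In KO females Cyp3a9 rose by 8.25 ± 0.49, and Cyp3a2 (-6.97 ± 0.43) and Cyp2c11 (-6.40 ± 0.96) fell. In WT males Mup5 rose by 8.82 ± 0.46 to 502 ± 105 CPM, and Ltc4s, leukotriene C4 synthase, by 7.76 ± 0.51. Cyp4a2 rose by 4.09 ± 0.24, Dhrs7 by 5.23 ± 0.47 and Hsd3b5 by 5.32 ± 0.49. The sterol exporters Abcg5 (-3.93 ± 0.44) and Abcg8 (-4.20 ± 0.54) and Cyp2c12 (-4.16 ± 0.29) fell. In KO males Mup5 rose by 10.39 ± 0.52 and Stac3 by 7.82 ± 0.95, and Aqp7, a glycerol channel, fell by 6.27 ± 0.47. Of 13 female-biased genes 10 rose in WT females and 1 fell (11 and 1 adjusted over the list alone). Tested by camera, it had adjusted p = 6.64e-06, and adjusted p = 0.195 with an estimated correlation. Of 22 male-biased genes 13 rose in WT males and 1 fell (14 and 1 adjusted over the list alone). Camera gave it adjusted p = 1.55e-10, and adjusted p = 0.127 with an estimated correlation. In KO males 18 rose (20 adjusted over the list alone). Camera gave it adjusted p = 2.25e-16, and adjusted p = 0.0222 with an estimated correlation. Cholesterol genes fell in 20 of 25 cases in KO females, 14 in WT males and 22 in KO males, with 0 higher by edgeR's test in each of the 3 groups (camera adjusted p = 5.72e-13, 3.43e-06 and 3.21e-15, and adjusted p = 0.195, 0.427 and 0.176 with an estimated correlation). Sample titles took another form at each age, so age and any batch of animals or libraries cannot be told apart in these 4 comparisons. The authors' deposited log2 table carries no scaling between libraries and moved the median fold change of all genes by -0.12 in WT females, -0.16 in KO females, -0.16 in WT males and -0.19 in KO males. It left 26%, 17.3%, 20.7% and 15% of the calls higher against 48.3%, 46.9%, 49.8% and 49.2% here. Upper-quartile scaling left 36.6% higher in WT females and 39% in WT males.

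The difference of the KO effect between the ages was also tested as an interaction. In females 326 genes passed that age-by-genotype test, 156 more positive and 170 more negative at 60 than at 30 days. Of 100 splits of the libraries 2 called as many, the real one included. The highest other called 349, so chance is not excluded for this count. In males 1 gene differed by that test, Cebpb (-1.37 ± 0.23, adjusted p = 0.0269), with 588 at an unadjusted p below 0.05 and 18 called by DESeq2. Upper-quartile scaling left 61.4% of the female calls more positive against 47.9% here. Cholesterol synthesis stood out in females, with 16 of 25 genes more negative at 60 days and 0 more positive (22 adjusted over the list alone). By camera the list had adjusted p = 6.65e-24, and adjusted p = 0.0932 with an estimated correlation. Hmgcs1 was at 1217 and 1888 CPM in WT and KO females at 30 days and at 1340 and 399 CPM at 60 days (-2.38 ± 0.34). Idi1 (-2.50 ± 0.46), Cyp51 (-1.49 ± 0.26) and Dhcr7 (-1.27 ± 0.23) showed the same direction. Pfkfb1 (-2.81 ± 0.34, adjusted p = 8.2e-05), Cyp1a2 (-1.15 ± 0.23), Cyp2d3 (-1.31 ± 0.26), Abcb4 (-0.81 ± 0.14) and Itih3 (-0.53 ± 0.12) were more negative at 60 days. Sparc (0.75 ± 0.14), Col5a1 (0.79 ± 0.17) and Sult2a2 (7.56 ± 1.53) were more positive. Stellate genes had 5 of 15 more positive (7 adjusted over the list alone). By camera the list had adjusted p = 1.06e-06, and adjusted p = 0.131 with an estimated correlation. The cell cycle list had 2 of 28 more positive (25 adjusted over the list alone). Its camera adjusted p was 8.45e-10, and adjusted p = 0.359 with an estimated correlation. Pericentral genes had 2 of 14 more negative (9 adjusted over the list alone). For the list, camera gave adjusted p = 1.35e-06, and adjusted p = 0.0932 with an estimated correlation. Leaving out 1 library gave 191 genes at the fewest, without replicate 1 of the 60-day KO females, where Rp1 (0.315) and Egflam (0.314) lost their calls, and 595 at the most, without replicate 1 of the 60-day WT females. In males Cebpb was lost in 11 of the 16 such fits, with adjusted p = 0.126 without replicate 1 of the 60-day KO males.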

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

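The tests of retina, brain myelin, shared reads, linked genes, the left-out library and the clock score, and the mean of the 4 KO contrasts, were chosen only after the result was seen; the counts of other splits were planned.

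Among 136 group values (17 measures in 8 groups), 3 lay further from their group than Dixon's 95% critical value for 4 samples, where chance gives about 5%. The summed level of retina genes was 2374.6 CPM in replicate 1 of the 60-day KO females, and Nr3c1 was at 244.55 CPM in replicate 4 of the 60-day WT males. Hsd11b1 was at 9.51 CPM in replicate 3 of the 60-day WT females. The interaction tests called 15 genes for the sexes at 60 days, 326 for the ages in females and 1 for the ages in males. Chance is not excluded for any of these counts, as given below. The clock score (evening minus morning genes) was higher in KO than in WT without overlap in 30-day females (by 0.64), 30-day males (by 0.44) and 60-day females (by 1.02; two-sided exact permutation p = 0.0286 and adjusted 0.0381 in each). It was higher by 0.23 in 60-day males, which did not pass the test (two-sided exact permutation p = 0.371). With the score as a covariate the count went from 33 to 3 genes in 30-day females, from 6 to 2 in 30-day males, from 23 to 19 in 60-day males, from 2037 to 1062 for the sexes in 60-day KO liver, and from 343 to 26 in the mean of the strata. Fold changes of the called genes kept shares of 0.981, 1.04, 1.01, 0.864 and 0.888 in the same order, and their SE grew 1.15, 1.05, 1.02, 1.29 and 1.40 times. Serpina6 dominates the share in 30-day males. Median sizes went from 1.191 to 1.063, 0.75 to 0.689, 0.699 to 0.688, 0.57 to 0.495 and 0.269 to 0.225 in that order.

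Retina transcripts in 1 liver library were the first pattern weighed. Of 24 measured retina genes 24 had their highest level of all 32 libraries in replicate 1 of the 60-day KO females, and RNA of retina in that library may be the source. Of 10 brain myelin genes 1 was highest there, which argues against RNA of brain tissue. In 2 of 24 retina genes the median of the other 3 KO females lay above the highest WT female, which argues against retina genes raised by the knockout. Whether such RNA entered with the tissue, the extraction or the sequencing was not tested.

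Serpina5, higher in KO than in WT liver, was the second. Its mean fold change over the 4 strata was 1.776, and the KO libraries lay above the WT libraries without overlap in each stratum, though in males it did not pass the test at 30 (0.93, adjusted p = 0.659) or 60 days (1.38, adjusted p = 0.153). Reads shared with Serpina6 would have made Serpina5 fall, as Serpina6 did. Neighbours were taken by their position in a RefSeq gene table. Of the 40 measured neighbours of Serpina6 4 changed in the mean of the strata, but Serpina5, which prompted the test, was 1 of them. Of 9399 windows of that size 13.45% held as many as the other 3 (median 1). The count therefore decides nothing on variants linked to the edited locus, and these stay open, as does, untested, an effect of CBG loss itself.

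The count of 745 genes in 60-day females was the third. Without the library with retina transcripts 399 genes changed, 373 of them (50.1% of the 745) among the 745, which argues against that library as the whole cause. Without replicate 2, 3 or 4 of the KO females 733, 667 and 669 changed, with 79.9%, 75.6% and 73.4% of the 745 kept. The count thus depended more on that library than on any other KO female. Without 1 WT female it ranged from 412 (51.1% kept) to 978 (88.9% kept). With the clock score as a covariate 132 genes changed, 112 of them among the 745, and the fold changes of the 745 kept a share of 0.607 (median size 0.64 before and 0.52 after) while their SE grew 1.30 times. Time of day at collection and the knockout cannot be told apart for these genes, as no collection times were given and the score moves with the genotype in 3 of the 4 strata. An effect of CBG on the clock or on the liver in adult females stays open, untested.

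Chance was weighed by splitting the same libraries otherwise, and is called excluded below only where no other split called as many genes. No adjustment was made over the contrasts, and 1 of 35 is the smallest share that 35 splits allow. For KO against WT it can be excluded in 30-day females (33 genes, at most 5 in the other 34 of 35 splits) and 60-day females (745 against at most 246). In 30-day males 6 genes stood against at most 2, but Serpina6, which the knockout itself fixes, was 1 of the 6. Of the other 5, 0 kept their call in all 8 fits that left out 1 library. Chance is therefore not called excluded for those 5. It cannot be excluded in 60-day males (23 genes, and 2 of 35 splits as large, the highest other 55). It can be excluded for the sexes (WT 30 days 228 against 24, KO 30 days 246 against 1, WT 60 days 2901 against 717, KO 60 days 2037 against 288). It can also be excluded for the ages (WT females 3643 against 738, KO females 2498 against 387, WT males 3466 against 212, KO males 3127 against 3). For the sex-by-genotype test at 30 days the splits decide nothing, since the real count was 0 (606 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom) and all 100 splits reach that by construction (highest 18). At 60 days chance cannot be excluded (15 genes, 10 of 100 splits as large, highest 188). For age by genotype in females 2 of 100 splits were as large (326 genes, highest other 349). That share is below 0.05, but 1 other split called more genes than the real one, so chance is not excluded. In males it cannot be excluded either (1 gene, 15 of 100 splits, highest 8). For the mean of the 4 strata it can be excluded (343 genes against at most 102, 1 of 100 splits).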

How the results depend on the processing

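Leaving out 2 libraries together, the mean of the 4 strata, the list tests with libraries left out, the divided WT females and the counts without Serpina6 were chosen only after the result was seen. For 33 results 519 alternatives gave 408 labelled the same, 1 stronger, 106 moved and 4 reversed. For counts of genes or lists, the same meant within a fixed factor of the count reported first. For shares toward the other sex it meant within the SD over the choices of WT libraries. For Serpina6, the sex score and named genes it meant the same direction and side of the threshold. For 884 values of named genes 15999 alternatives gave 14438 the same, 1526 weaker and 35 reversed, with no called gene among them. Why values moved was not tested.

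Genes changed by KO in 30-day females (33) were 18 with no filter, 92 by DESeq2, 15 from the authors' log2 table, 50 with 16 libraries, 8 with 8 libraries, 8 with the title covariate, and 4 to 60 with 1 library left out. In 30-day males (6) they were 26 by DESeq2, 16 with 16 libraries, 5 with 8 (1 of the 6 kept), 8 with the title covariate (3 kept) and 1 to 7. In 60-day females (745) they were 277 with 16 libraries, 56 with 8, and 399 to 978. In 60-day males (23) they were 15 with no filter, 65 by DESeq2, 4 from the authors' table, 4 with 16 libraries, 8 with 8, and 2 to 46. Between the sexes they were 358 with 16 libraries and 119 to 209 in WT at 30 days (228). They were 403 by DESeq2, 401 with 16 libraries, 461 with 8, 110 with the title covariate and 124 to 225 in KO at 30 days (246). With 8 libraries they were 1914 in WT (2901) and 1333 in KO (2037) at 60 days. For sex by genotype at 60 days (15) they were 94 by DESeq2, 9 by limma-voom, 2 with 16 libraries, 112 with 2 left out and 5 to 126. For age by genotype they were 584 by DESeq2 and 191 to 595 in females (326), 18 and 0 to 2 in males (1). For the mean of strata (343) they were 557 by DESeq2 and 211 to 430.

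The KO difference of the sex score ranged from -0.509 to 0.147 in 30-day females, was 0.102 with medians in 30-day males, and 0.656 in 60-day females with genes called sex-biased in WT. The same WT females served both steps there, which by itself moves the score toward males, and with WT libraries divided the mean was 0.416. The share of KO calls toward the other sex was 85.38% with all WT females (75.1%). In males (30%) it was 72.22% with all WT males, and the 0% at a log2 fold change of at least 1 was Serpina6 alone in each of 6 choices and says nothing of other genes. Lists past the threshold were, with an estimated correlation and by fry, 0 and 2 in 30-day females (9), 0 and 1 in 30-day males (9). They were 2 and 5 in 60-day females (11), 0 and 2 in 60-day males (8), 0 and 0 for sex by genotype at 30 days (6) and 0 and 1 at 60 days (10). With 1 library left out they were 5 to 10, 7 to 14, 5 to 10 and 5 to 10 in 30-day males, 60-day females, 60-day males and sex by genotype at 30 days.

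Uncalled genes that reversed follow, with the range over fits that left out 1 library. Nr3c1, KO vs WT, F 30 d was -0.003 with upper quartile and ranged from -0.025 to 0.069. Cyp2c12, KO vs WT, M 30 d was -0.004 with the title covariate and ranged from -0.226 to 0.322. Ghr, KO vs WT, M 30 d ranged from -0.034 to 0.068 and Igf1, KO vs WT, M 30 d from -0.046 to 0.039. Nr3c1, KO vs WT, F 60 d was 0.003 with upper quartile, 0.039 with 2 left out, and ranged from -0.124 to 0.046. Igf1, KO vs WT, F 60 d was 0.001 and 0.026 and ranged from -0.129 to 0.037. Hsd11b1, KO vs WT, F 60 d was -0.003 with DESeq2's factors, -0.004 with no filter, -0.008 by DESeq2 and -0.095 by limma-voom. It was -0.144 from the authors' table, -0.004 with 16 libraries, and ranged from -0.457 to 0.291. Cyp2c11, KO vs WT, M 60 d ranged from -0.317 to 0.055 and Nr3c1, KO vs WT, M 60 d from -0.242 to 0.002.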

Other observations

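The mean of the 4 KO contrasts and the pineal list were tests chosen only after the result was seen.

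Averaged over both sexes and ages, 343 genes differed between KO and WT liver, 151 higher and 192 lower, and 8 of them by a log2 fold change of at least 1 in size. Next to Serpina6 (-3.50 ± 0.13), Hdc, the histamine-forming enzyme (1.40 ± 0.23), Igsf9 (0.93 ± 0.17), Per3 (0.89 ± 0.16), Ccnd1, a cyclin (0.73 ± 0.17), Per2 (0.71 ± 0.14), Srebf1 (0.47 ± 0.10) and Epcam (0.29 ± 0.05) were higher. Lower were Apoa4 (-0.88 ± 0.15), Slc1a2 (-0.83 ± 0.18), Orm1 (-0.76 ± 0.14), Gpt (-0.67 ± 0.13), Pfkfb1 (-0.60 ± 0.11), Serpina3n (-0.54 ± 0.11), Saa4 (-0.49 ± 0.07), Ass1 (-0.43 ± 0.07), Xbp1 (-0.38 ± 0.06), Cyp1a2 (-0.37 ± 0.08), Hp, haptoglobin (-0.33 ± 0.07), Npas2 (-0.31 ± 0.08) and Fbp1 (-0.18 ± 0.04). Each of these genes passed the test in all 32 fits that left out 1 library. A call in this mean does not show a change in every stratum. For Pfkfb1, Srebf1 and Slc1a2, for example, the fold changes given above for 60-day females were larger in size than the mean. Pfkfb1 stood at similar levels in KO and WT males of 60 days. The authors' deposited log2 table left 78.1% of the calls higher against 44% here, and with the clock score as a covariate 26 genes changed, 23 of them among the 343, while the fold changes of the 343 kept a share of 0.888 and their SE grew 1.40 times. The median size of these fold changes went from 0.269 to 0.225.

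Of 23 acute phase genes 7 were lower and 0 higher in this mean (8 adjusted over the list alone; camera adjusted p = 3.3e-06, and adjusted p = 0.318 with an estimated correlation). Of 24 urea cycle genes 2 were lower and 0 higher (7 adjusted over the list alone; camera adjusted p = 7.29e-07, and adjusted p = 0.418 with an estimated correlation), and of 25 interferon genes 1 was higher, with all 25 fold changes positive (6 adjusted over the list alone; camera adjusted p = 5.78e-09, and adjusted p = 0.451 with an estimated correlation). Of 6 pineal gland genes 1 had its highest level in the library with retina transcripts.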
